A study of Mus musculus with 24 samples.

How the data were processed

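RNA from mouse macrophages was measured on 24 Affymetrix expression arrays, 1 array per sample, each carrying 45101 probe sets. The deposited values are on the log2 scale and were made by the authors with RMA, per the submitters' processing notes, version not given. RMA corrects the background of each array, gives all arrays the same distribution of probe intensities and summarises the probes of a probe set into 1 value. It therefore removes differences in total signal between arrays, and a change is relative to the other genes on the array. The deposited table was used as it stands, with values between 1.94 and 14.15. The genome build is not given in the sources used here, and scanner images were not analysed here.

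Probe sets were named from the platform annotation. Of the probe sets, 64 were Affymetrix controls, 34945 had 1 gene symbol, 932 had several and 9160 had none. Symbols were looked up by gene identifier in a RefSeq table of the mouse assembly GRCm38.p6, used for names only. It held 34741 of the identifiers and lacked 204, and 0 symbols changed. For each gene the probe set with the highest mean over all arrays was used, which gave 18193 genes, and 9010 of these had more than 1 probe set. A gene was tested when its highest group mean lay above the median of all values, 4.70, which kept 12063 genes and left out 6130. No fold is given where the lower of the group means compared lay below this level, or at it, because the size of such a change depends on the background. Unstimulated Egr1 (4.92), Cxcl10 (4.87) and Acod1 (4.78) lay just above it, so the sizes of their folds may depend on the background too. The 42 spike-in probe sets among the controls, from bacterial and phage RNA added to every sample, were kept apart as a measure of handling.

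Groups were taken from the sample labels. One label disagreed with the others of its sample, as described with the samples, and its values were checked against both times it could belong to. The comparisons were each LPS time against unstimulated, 120 against 60 min and 360 against 240 min. They were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on mean level), with 1 mean per time over all 24 arrays and 5.34 prior degrees of freedom. Tests were two-sided, p values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p below 0.05. Errors of log2 changes are standard errors (SE) from this fit, and errors of group means are standard deviations (SD). A moderated F test asked for any change over the 18 arrays of 0 to 120 min. The number of arrays limits the precision. Nothing in the labels says that replicates came from separate cultures or animals, so p values measure the spread between these samples, which may be technical.

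Gene lists were tested with limma's camera, which asks whether the genes of a list moved more than other genes, with a preset correlation between members of 0.01 and again with the correlation estimated for each list. List p values were adjusted over the lists within a comparison. There were 21 pathway lists and 10 lists of markers of macrophages and other bone marrow cells. The annotation lacked 45 of 484 entries of the pathway lists and 11 of 90 of the marker lists, which were not analysed here. A list needed 3 tested genes, so 28 lists were tested. The genes named in the text are the 10 largest rises and 6 largest falls among called genes whose groups of arrays did not overlap, a list of 32 focal genes of the LPS response whatever their result, and the members with the largest change from each list. Genes with clone or predicted-gene symbols were counted but not named. Of the focal genes 31 were measured, and Nfkb1 was not analysed here. The comparisons, tests, gene lists, naming rule and first set of alternatives were fixed before the data were examined.

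Replicates of 0 to 120 min are numbered 1 to 3 in the labels. The numbers were checked by correlating the deviations of arrays from their group means. All 45 pairs with the same number correlated at 0.167 or more, with a median of 0.337, against a median of -0.170 between numbers, and 18 of 18 arrays correlated best with their own number. These numbers were therefore taken to pair the arrays, from the data and not from a statement in the labels. The fit without the number is given first, with the fit that has the number as a block beside it where a call or count moved.

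The alternatives were eBayes without a trend or with robust weights, array weights, a filter at the 75th percentile of all values (6.73) or no filter, the mean of a gene's probe sets, repeated quantile normalization, fits to the groups compared or to arrays of the same title pattern alone, the replicate number as a fixed or random block, random lists matched on mean level in place of camera, the F test on all 24 arrays, and leaving out each array in turn. Fits with parts of the 240 min group, and a fit without 80 min replicate 2 and 240 min B, which were low in 5' spike signal, were chosen after seeing the data. The main steps were tested on simulated data of the same size with known changes in 66 or 67 genes per size. At log2 changes of 0.5, 1 and 2, the test recovered 53.0%, 94.0% and 100% of the changed genes for 60 min against unstimulated, 43.9%, 91.0% and 100% for 240 min, and 43.9%, 95.5% and 100% for 360 against 240 min. Genes simulated without a change made up 2.94%, 7.10% and 6.43% of the calls. The simulated noise was independent, with 1 spread per gene for all groups and no replicate pairs. In the real data the median SD of a gene was 0.208 at 240 min against 0.0911 to 0.137 at the other times. The simulated rates need not hold for the comparisons with 240 min. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.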

Results

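The series followed the response of mouse bone marrow-derived macrophages to lipopolysaccharide (LPS), the cell wall component of Gram-negative bacteria that is sensed by Toll-like receptor 4. Cells from femurs of C57BL/6 mice, all 24 samples labelled female, were grown for 7 days with M-CSF, the growth factor that drives marrow progenitors to become macrophages, and then given LPS at 10 ng/ml. Arrays covered unstimulated cells and 20, 40, 60, 80 and 120 min of LPS with 3 samples each, 240 min with 4 and 360 min with 2. The 4 arrays of 240 min are named A, B, C and WT, and those of 360 min A and B. Titles at 240 and 360 min follow another pattern than those of 0 to 120 min and have no unstimulated sample of their own, so title pattern and late time cannot be told apart. The question taken from the design is which transcripts change at each time after LPS.

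For the first sample of 20 min, the treatment label gave 120 min where its title, description and source gave 20 min. Over the 462 genes changed at least 2-fold at 120 min, it differed from the other 20 min arrays by 0.173 on average (log2) and from the 120 min arrays by 1.87, and it was kept at 20 min. No pair of arrays in a group held identical values, and arrays within a group correlated at 0.980 to 0.997 across genes. The first principal component, which separated the late arrays from the rest, held 75.8% of the variance. Median values of the macrophage markers, among them Csf1r, Adgre1 and Cd68, stayed between 11.94 and 12.34 at every time. Those of B cell, T cell, NK cell, neutrophil, erythroid, megakaryocyte, mast cell, dendritic cell and stromal markers lay between 3.65 and 5.95. None of the 7 marker lists with enough tested genes was called in any comparison (lowest adjusted p = 0.0523, neutrophil markers at 80 min, and 0.0191 there with the replicate block). The NK cell, erythroid and mast cell lists had 2 tested genes each and were not tested.

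At 20 min, LPS had raised transcripts of rapidly induced regulators and of a few secreted proteins. Cxcl2, a chemokine that attracts neutrophils, rose 20.8-fold (log2 change 4.38 ± 0.22 SE, n = 3 and 3), and the transcription factor Egr1 rose 10.4-fold (3.38 ± 0.34). Tnf, the gene of tumour necrosis factor, rose 5.05-fold (2.34 ± 0.16), and Socs3, an inhibitor of cytokine signalling, gained 2.11 ± 0.17 from an unstimulated value of 4.15, below the filter level of 4.70. Zfp36, which promotes decay of inflammatory transcripts, gained 2.04 ± 0.22, and Nfkbia, the NF-kB inhibitor that is itself an NF-kB target, gained 1.41 ± 0.09. Of 12063 genes tested with limma, 14 were higher and 0 lower, and 150 passed an unadjusted p of 0.05. Unchanged genes with well-calibrated p values would pass that limit at a share of about 0.05. The 150 here, and the 444 at 40 min, lay below that share. Counts at these times may therefore be too low and first calls too late, and the cause was not tested. Fos (1.71 ± 0.34) passed at an adjusted p of 0.0497 and kept its call without 1 array only when that array was 120 min replicate 2 or 240 min A, C or WT.

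By list, 7 of 32 immediate early and MAPK-responsive genes rose at 20 min (13 adjusted over the list alone), with Btg2 at 2.30 ± 0.30 beside Egr1 and Zfp36 (list adjusted p = 4.76e-35). The NF-kB list held subunits and inhibitors of NF-kB and also other genes, such as Socs3, Birc3, Cflar and Nlrp3, and its members are called NF-kB genes below. Of its 21 tested genes 3 rose (4 adjusted over the list alone, list adjusted p = 5.30e-18). Among 21 chemokines 2 rose, Cxcl2 and Ccl4 (4 adjusted over the list alone, list adjusted p = 3.72e-10). Ccl4 (0.83 ± 0.14, adjusted p = 0.00967) lost its call without unstimulated replicate 1 or 3 (adjusted p = 0.119 and 0.0517) or 20 min replicate 1 or 2 (adjusted p = 0.0705 and 0.0971). The RNA decay regulators Btg2 and Zfp36 rose among 16 listed (2 adjusted over the list alone, list adjusted p = 2.17e-11). Both are also in the immediate early list, so these list tests are not independent. Of 22 cytokines and growth factors Tnf alone rose (3 adjusted over the list alone; adjusted p = 4.76e-05, and adjusted p = 0.164 with an estimated correlation). The interferon-stimulated genes were called as a list at a median of 0.10 with 0 of 40 members called (0 adjusted over the list alone), at adjusted p = 1.52e-05 and adjusted p = 0.306 with an estimated correlation. With the replicate block 29 genes were called, among them Cxcl1 (1.59, adjusted p = 0.000511, against 0.0753) and Il10 (0.61, adjusted p = 0.0417), and the list of macrophage lineage transcription factors passed (adjusted p = 0.0409, against 0.127). Cxcl1 was also called without 20 min replicate 3 (adjusted p = 0.00994), 40 min replicate 3 (0.0457) or 240 min C (0.0202) or WT (0.0198).

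**Figure D1:**
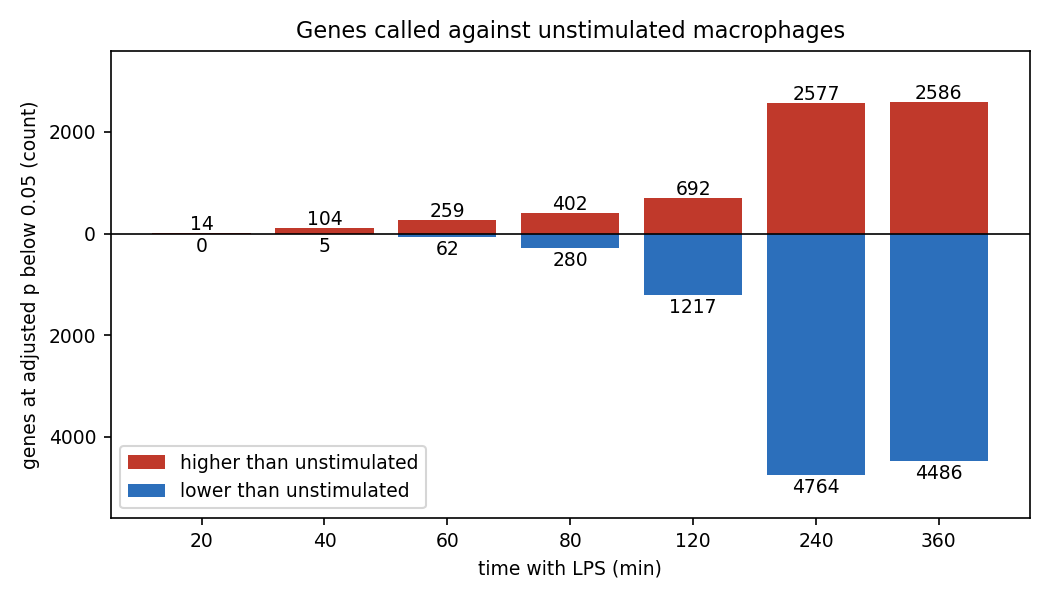
Number of genes called higher and lower against unstimulated cells (limma, adjusted p below 0.05) at each LPS time in minutes. The calls went from 14 higher and 0 lower at 20 min to 692 higher and 1217 lower at 120 min, and to 2577 higher and 4764 lower at 240 min, where the arrays also have another title pattern.

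At 40 min, Egr1 stood 98.6-fold above unstimulated cells (6.62 ± 0.34, from 4.92, just above the filter level). Nfkbiz, a nuclear cofactor of NF-kB, stood 85.4-fold above them (6.42 ± 0.26). Cxcl2 (6.04 ± 0.22), Socs3 (5.88 ± 0.17) and Cxcl1 (4.51 ± 0.34) followed. The first rises of Il10 (2.91 ± 0.26), the anti-inflammatory cytokine, of Ptgs2 (3.08 ± 0.17, from 2.95, near background), the inducible cyclooxygenase, and of Il1b (2.14 ± 0.38) were called here in the fit without the block, as was that of Irf1 (2.20 ± 0.24). The test called 104 genes higher and 5 lower. Rpl12, a ribosomal protein gene, fell by 1.20 ± 0.17. Rbx1 fell by 0.84 ± 0.17 (adjusted p = 0.00775) and lost its call without unstimulated replicate 2 or 3 or 40 min replicate 2 (adjusted p = 0.0625, 0.0747 and 0.108). With the replicate block 230 genes were called, now with Acod1 (0.82, adjusted p = 0.00991) and Cebpb (0.69, adjusted p = 5.48e-06, against 0.0567). Cebpb was also called without 240 min B, C or WT (adjusted p = 0.00724, 0.00133 and 0.0455).

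Of the immediate early genes 22 of 32 rose at 40 min (24 adjusted over the list alone; adjusted p = 1.10e-102). They included Fos (3.34 ± 0.34), Junb (3.59 ± 0.17), a component of AP-1, and Phlda1 (4.29 ± 0.44). The NF-kB list had 11 of 21 higher (14 adjusted over the list alone; adjusted p = 1.83e-59), led after Nfkbiz and Socs3 by Tnfaip3 (3.66 ± 0.16), a deubiquitinase that limits NF-kB activity. Chemokines had 7 of 21 higher (8 adjusted over the list alone; adjusted p = 1.66e-23) and cytokines 5 of 22 (5 adjusted over the list alone; adjusted p = 1.10e-17), including Tnfsf9 at 3.58 ± 0.24. The nitric oxide and itaconate list was called only with the replicate block (adjusted p = 0.00679, against 0.0587).

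At 60 min Nfkbiz stood 140-fold above unstimulated cells (7.13 ± 0.26), Socs3 had gained 7.14 ± 0.17 from its unstimulated value of 4.15, below the filter level, and Tnf had reached 35.3-fold (5.14 ± 0.16). Cxcl10, a chemokine of the interferon response, gained 5.67 ± 0.22, and Acod1, the enzyme that makes itaconate, rose 11.6-fold (3.54 ± 0.25). Egr1 stood at 6.93 ± 0.34, Fos at 3.50 ± 0.34 and Jun at 1.52 ± 0.21. Calls were 259 higher and 62 lower, of which 143 and 13 reached 2-fold. The largest falls included Txnip (-1.94 ± 0.31), an inhibitor of thioredoxin and glucose uptake, and the zinc finger genes Zfp950 (-1.42 ± 0.19) and Zfp472 (-1.20 ± 0.19). With the replicate block 846 genes were called, 563 higher and 283 lower. They included Il6 (0.71, adjusted p = 0.0296) and Ifnb1 (1.33, adjusted p = 1.33e-05), which were not called without it (adjusted p = 0.247 and 0.566). Il6 was also called without 80 min replicate 1 (adjusted p = 0.0305) and Ifnb1 without 240 min WT (adjusted p = 3.86e-05).

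Among the lists at 60 min, 25 of 32 immediate early genes (25 adjusted over the list alone; adjusted p = 7.12e-80) and 15 of 21 NF-kB genes rose (17 adjusted over the list alone; adjusted p = 2.17e-61). So did 10 of 21 chemokines (11 adjusted over the list alone; adjusted p = 2.29e-24) and 8 of 22 cytokines (10 adjusted over the list alone; adjusted p = 3.17e-20). The RNA decay list had 6 of 16 higher (9 adjusted over the list alone; adjusted p = 6.16e-15), with Zfp36 at 4.09 ± 0.22 and the endonuclease gene Zc3h12a at 1.71 ± 0.22. MHC class II and co-stimulation genes had 4 of 13 higher (4 adjusted over the list alone; adjusted p = 2.49e-08). Those led by Cd83 (3.28 ± 0.28) and Icam1 (2.17 ± 0.24) are co-stimulatory or adhesion molecules and not class II genes. Egr2 (3.87 ± 0.36), also in the immediate early list, and Bcl6 (1.12 ± 0.22) were among 3 of 16 macrophage lineage transcription factors that rose (3 adjusted over the list alone, list adjusted p = 0.000918). Of the apoptosis regulators 5 of 16 rose (5 adjusted over the list alone, list adjusted p = 1.09e-05), led by the inhibitor of apoptosis Birc3 (1.36 ± 0.14). The pro-apoptotic genes Bcl2l11 (1.17, adjusted p = 0.0157) and Pmaip1 (1.08, adjusted p = 0.0112) rose as well. These 2 lost their calls in 4 and 3 of the 24 fits without 1 array, so the list gives no single direction for cell survival.

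**Figure D2:**
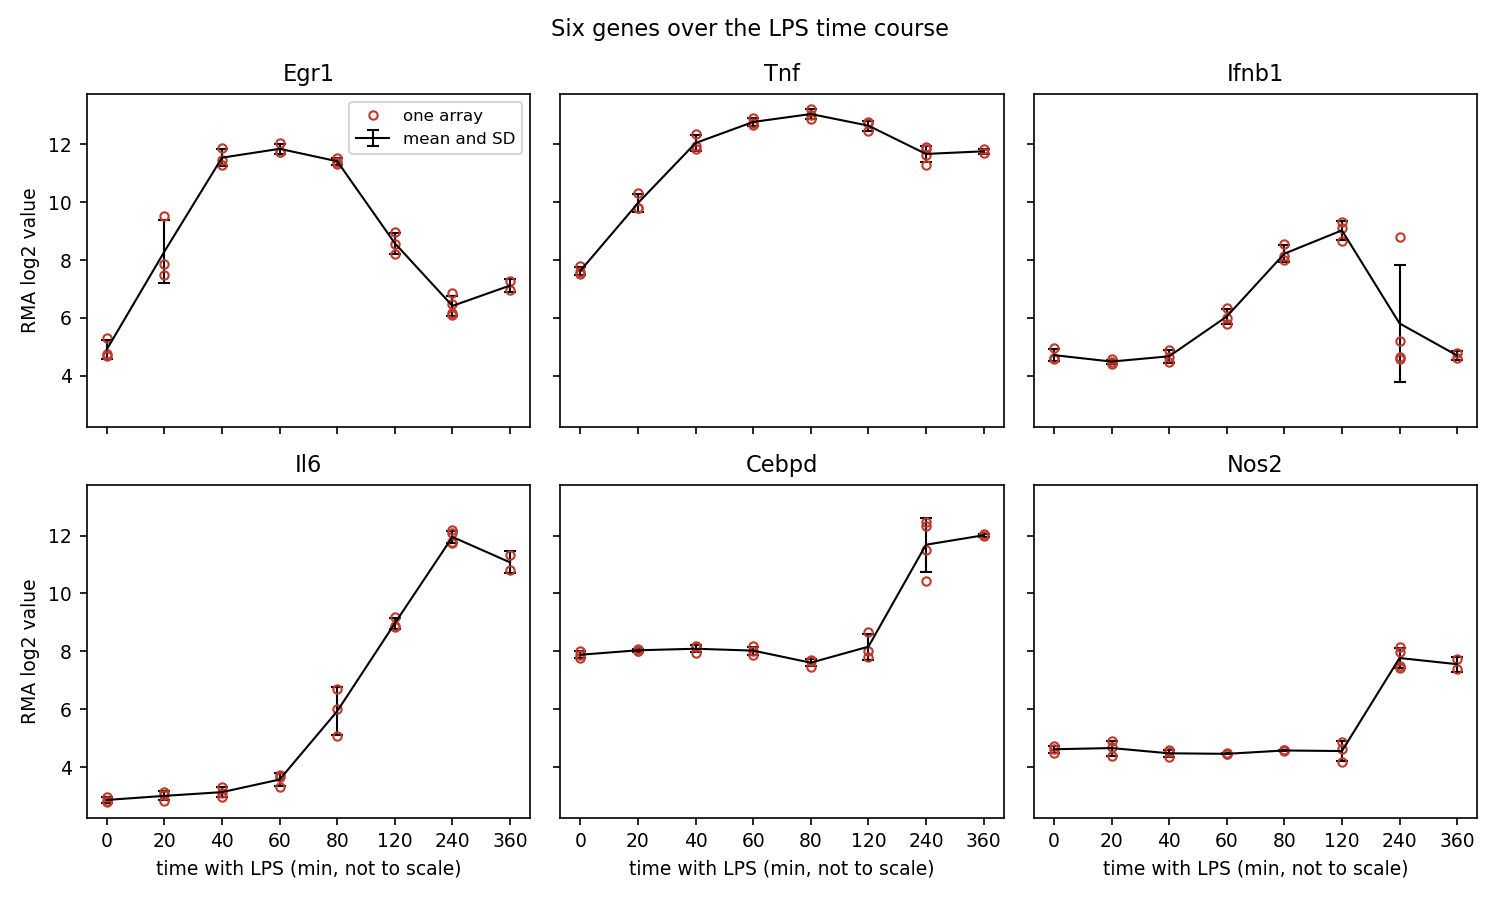
Log2 expression values of Egr1, Tnf, Ifnb1, Il6, Cebpd and Nos2 on each array (points) with group means and SD (n = 3 to 120 min, 4 at 240 min, 2 at 360 min) against LPS time in minutes, with the time axis not to scale. Egr1 peaked at 11.84 at 60 min, Ifnb1 at 9.03 at 120 min and Il6 at 11.95 at 240 min, while Cebpd and Nos2 were near their unstimulated levels up to 120 min.

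At 80 min Il6 (3.07 ± 0.25) and Ifnb1 (3.50 ± 0.64), the gene of interferon beta, passed the test. Unstimulated Il6 (2.86) lay near background and Ifnb1 (4.72) at the filter level, so the sizes of their changes depend on the background. Ccl5 gained 3.91 ± 0.24, and Rel, an NF-kB subunit, rose 6.39-fold (2.68 ± 0.17). Il12b, a subunit of interleukin 12, stood at 1.67 ± 0.38 (adjusted p = 0.00648, and 0.0738 without 80 min replicate 2). Calls were 402 higher and 280 lower (58.9% higher). The replicate block gave 770 higher and 1329 lower (36.7% higher), so most calls were then lower, and it added Csf3 (0.33, adjusted p = 0.0302). Csf3 lay below the filter level in both groups (3.72 unstimulated and 4.05 at 80 min). The share of higher genes was also below that of lower ones with array weights (42.5%), the random block (45.9%) and the mean of a gene's probe sets (49.9%). Txnip (-2.55 ± 0.31), Zfp472 (-1.96 ± 0.19), Zfp53 (-1.95 ± 0.26), Zfp748 (-1.74 ± 0.20) and Cnr2 (-1.64 ± 0.13), a cannabinoid receptor gene, had the largest falls.

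Of 40 interferon-stimulated genes, 8 were higher and 1 lower at 80 min (10 and 1 adjusted over the list alone). At 40 min 0 of 40 were called in limma's test (1 adjusted over the list alone), with the list at adjusted p = 0.00522 and adjusted p = 0.504 with an estimated correlation. At 80 min Rsad2, which encodes the antiviral protein viperin, stood at 2.20 ± 0.17, Oasl1 1.81 ± 0.19 and Ifit1 1.55 ± 0.28. The list then passed at adjusted p = 1.02e-06, and had an adjusted p = 0.131 with an estimated correlation. Of cytokines 13 of 22 rose (15 adjusted over the list alone; adjusted p = 2.94e-29), and of chemokines 12 of 21 (12 adjusted over the list alone; adjusted p = 1.23e-26). Of NF-kB genes 16 of 21 rose (18 adjusted over the list alone; adjusted p = 2.19e-54) and of immediate early genes 25 of 32 (25 adjusted over the list alone; adjusted p = 1.20e-60). The heat shock list passed at adjusted p = 0.000674 (adjusted p = 0.0639 with an estimated correlation) on 2 of 13 members (3 adjusted over the list alone), Hspa1a (2.32 ± 0.24) and Hspa1b (2.10 ± 0.19), the near-identical inducible Hsp70 genes. Macrophage identity genes passed only with the replicate block (adjusted p = 0.0430, against 0.0920).

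At 120 min Cxcl10 stood 197-fold (7.62 ± 0.22), Acod1 147-fold (7.20 ± 0.25) and Il1b 88.2-fold (6.46 ± 0.38) above unstimulated cells. Unstimulated Cxcl10 (4.87) and Acod1 (4.78) lay just above the filter level, so the sizes of their folds may depend on the background. Socs3 (7.90 ± 0.17), Il6 (6.10 ± 0.25) and Il12b (4.89 ± 0.38) were raised from unstimulated values of 4.15, 2.86 and 4.04, below the filter level, and Ifnb1 gained 4.31 ± 0.64. The number of lower genes, 1217, exceeded that of higher genes, 692, although 128 lower against 334 higher genes changed at least 2-fold. The largest falls included Dusp6 (-3.80 ± 0.29), a phosphatase of ERK, Arrdc3 (-2.59 ± 0.20), the homeobox gene Hhex (-2.57 ± 0.24) and the surface receptor gene Cd300lb (-2.26 ± 0.15). Jun lay below its unstimulated level (-1.13 ± 0.21, adjusted p = 0.000369). Csf3 (0.28 ± 0.13), Cebpd (0.28 ± 0.32), Nos2 (-0.06 ± 0.18) and Csf1r (-0.05 ± 0.11) were not called (adjusted p = 0.168, 0.622, 0.861 and 0.823). With the replicate block 4600 genes were called, Csf3 and Fos (0.54) among them (adjusted p = 0.0347 and 0.0269).

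Of the interferon-stimulated genes 19 of 40 were higher and 1 lower at 120 min (21 and 3 adjusted over the list alone; adjusted p = 1.02e-15), with Rsad2 at 4.06 ± 0.17, Oasl1 at 4.05 ± 0.19 and Ifit1 at 3.77 ± 0.28. NF-kB genes had 18 of 21 higher (18 adjusted over the list alone; adjusted p = 1.15e-43), and chemokines 16 of 21 (16 adjusted over the list alone; adjusted p = 2.16e-27). Cytokines had 16 of 22 higher (16 adjusted over the list alone; adjusted p = 6.92e-28). Of the nitric oxide, itaconate and antioxidant effectors 10 of 14 rose (10 adjusted over the list alone; adjusted p = 1.03e-12), with the arginine transporter Slc7a2 at 3.08 ± 0.34 and the acute phase gene Saa3 at 2.03 ± 0.26. TLR and adaptor genes had 10 of 23 higher and 1 lower (12 and 3 adjusted over the list alone; adjusted p = 4.57e-06), led by Tlr2 (3.19 ± 0.16). Of 16 apoptosis regulators 7 were higher and 1 lower (8 and 2 adjusted over the list alone; adjusted p = 8.96e-05). The prostaglandin and leukotriene list passed at adjusted p = 0.0277 (0.0958 with the replicate block) on 3 of 13 genes (3 adjusted over the list alone), led by Ptgs2 (6.14 ± 0.17) and the receptor gene Ptger4 (3.25 ± 0.14). Its median was -0.04 where its mean, 0.71, and its test were positive. The oxidative phosphorylation list was lower at a median of -0.19 with 3 of 28 called (1 adjusted over the list alone), at adjusted p = 0.00366 and adjusted p = 0.529 with an estimated correlation. Cell cycle genes passed only with the replicate block (adjusted p = 0.00185, against 0.369), as did macrophage lineage transcription factors (adjusted p = 0.0422, against 0.0540).

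Between 60 and 120 min some early transcripts fell and several cytokine and interferon-stimulated transcripts rose. Egr1 (-3.26 ± 0.34), Fos (-2.96 ± 0.34), Jun (-2.65 ± 0.21) and Btg2 (-2.31 ± 0.30) fell, and Ier3 (-1.46 ± 0.21) and Zfp36 (-1.27 ± 0.22) were also lower. Ccl5 rose 27.0-fold (4.75 ± 0.24) and Rsad2 13.0-fold (3.70 ± 0.17), and Il6 (5.40 ± 0.25) and Il12b (4.79 ± 0.38) rose from 60 min values of 3.57 and 4.14, below the filter level. Tnf (-0.13 ± 0.16), Nfkbia (-0.04 ± 0.09) and Tnfaip3 (-0.14 ± 0.16) were not called (adjusted p = 0.668, 0.822 and 0.626). Of 32 immediate early genes 14 fell and 3 rose (15 and 5 adjusted over the list alone; adjusted p = 0.00377, and adjusted p = 0.343 with an estimated correlation). Higher were 17 of 40 interferon-stimulated genes (19 adjusted over the list alone; adjusted p = 3.09e-20) and 11 of 21 NF-kB genes (12 adjusted over the list alone; adjusted p = 1.35e-13), led by Rel (2.02 ± 0.17). Cytokines had 12 of 22 higher and 1 lower (13 and 2 adjusted over the list alone; adjusted p = 6.02e-13).

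The direct comparison of 120 and 60 min gave 500 higher and 836 lower genes (37.4% higher), and 594 higher and 580 lower (50.6% higher) after repeated quantile normalization. With the replicate block it gave 1033 higher and 2920 lower (26.1% higher), 3953 in all against 1336, and added the cell cycle (adjusted p = 0.00153, against 0.362) and apoptosis lists (adjusted p = 0.0499, against 0.0714). The total was 778 without 120 min replicate 2 and 787 without 60 min replicate 1. Of the 259 genes higher at 60 min, 232 were higher at 120 min too, where independent lists would share 14.9, and 32 fell between the times (17.9 for independent lists). Simulated unchanged groups shared 0 in both, a value that leaves out all effects and does not measure what the arrays in common add. The first pair of comparisons has the unstimulated arrays in common and the second the 60 min arrays, each too few to be divided, so part of each excess may come from them.

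Over 0 to 120 min the F test called 2706 genes, 930 of them with their largest change upward and 1776 downward, and 4722 with the replicate block. The largest change came at 20 min for 10 of the higher genes, at 40 min for 29, at 60 min for 90, at 80 min for 132 and at 120 min for 669. Of the lower genes, 1592 had it at 120 min. Those counts place each gene at its extreme group mean and test no order between times.

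**Figure D3:**
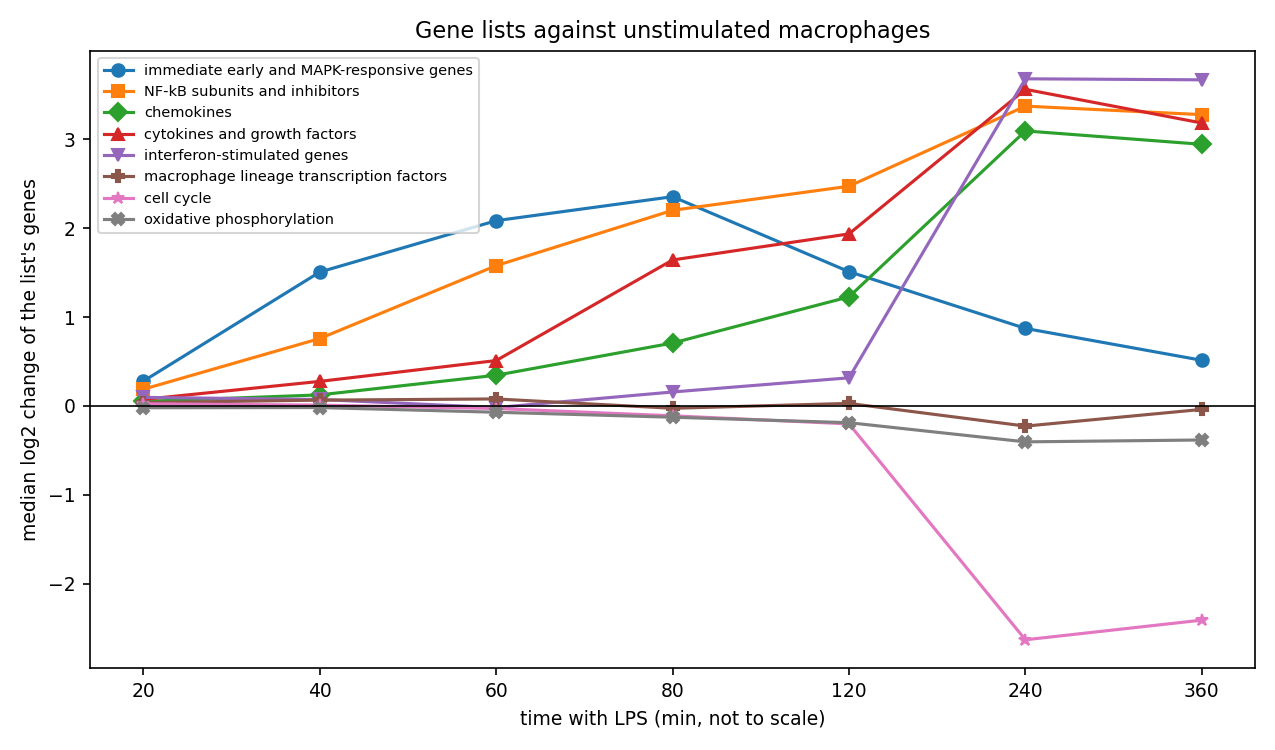
Median log2 change against unstimulated cells of 8 gene lists at each LPS time in minutes. The immediate early list has its highest median, 2.35, at 80 min, and the interferon-stimulated genes reach 3.68 and the cell cycle genes -2.63 at 240 min.

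At 240 min Cxcl10 stood 446-fold above unstimulated cells (8.80 ± 0.20, n = 4 and 3), from 4.87, just above the filter level. Ptgs2 (9.26 ± 0.16), Il6 (9.09 ± 0.24) and Ccl5 (8.76 ± 0.22) rose from unstimulated values of 2.95, 2.86 and 4.54, below the filter level, so the sizes of their changes depend on the background. Cd69, an activation antigen, gained 8.43 ± 0.21, and the interferon-induced GTPase gene Iigp1 8.07 ± 0.13. Cebpd (13.9-fold, 3.80 ± 0.30), a transcription factor, and Nos2 (3.15 ± 0.17), the inducible nitric oxide synthase, were called here for the first time, as was Csf3 in the fit without the block (0.55 ± 0.12, adjusted p = 0.000522). Unstimulated Nos2 (4.61) and both Csf3 means (3.72 and 4.27) lay below the filter level, so the sizes of these 2 genes' changes depend on the background. Ifnb1 was no longer called (1.10 ± 0.60, adjusted p = 0.119), with array WT at 8.81 and the others between 4.60 and 5.19, and passed without array A or B (adjusted p = 0.0369 and 0.0416). Lhfpl2 (-5.27 ± 0.19), Dusp6 (-4.97 ± 0.27), Irf2bp2 (-4.96 ± 0.13), Cd300lb (-4.84 ± 0.14), Gmnn (-4.67 ± 0.18), an inhibitor of DNA replication licensing, and Sesn1 (-4.50 ± 0.23) had the largest falls. Lhfpl2 ended at 3.54 to 4.42 on the 240 min arrays, below the filter level, so the size of its fall depends on the background.

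All 40 of the 40 interferon-stimulated genes were higher at 240 min (40 adjusted over the list alone; adjusted p = 1.25e-38), with Mx1 at 7.74 ± 0.26, Ifit1 at 7.67 ± 0.26 and Gbp2 at 7.06 ± 0.16. So were 21 of 21 NF-kB genes (21 adjusted over the list alone; adjusted p = 7.20e-18) and 13 of 14 nitric oxide and itaconate genes (13 adjusted over the list alone; adjusted p = 3.44e-10). Of 21 chemokines 19 were higher and 1 lower (19 and 1 adjusted over the list alone; adjusted p = 1.20e-13), and of 22 cytokines 16 and 1 (16 and 1 adjusted over the list alone; adjusted p = 9.04e-12). Of the C/EBP, ATF and IRF factors 13 of 21 rose and 4 fell (13 and 4 adjusted over the list alone; adjusted p = 6.42e-05), led by Irf7 (4.15 ± 0.14). Immediate early genes had 17 of 32 higher and 3 lower (18 and 3 adjusted over the list alone; adjusted p = 3.39e-05, and adjusted p = 0.148 with an estimated correlation). All 28 of the 28 cell cycle genes were lower (28 adjusted over the list alone), among them Rrm2 (-4.28 ± 0.37), Ccne2 (-4.21 ± 0.22) and Tk1 (-3.51 ± 0.21). That list passed at adjusted p = 3.85e-10 and had an adjusted p = 0.108 with an estimated correlation. Oxidative phosphorylation genes had 22 of 28 lower and 1 higher, Cycs (22 and 1 adjusted over the list alone; adjusted p = 0.00404, and adjusted p = 0.534 with an estimated correlation).

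The test called 2577 genes higher and 4764 lower at 240 min, and 1078 and 1451 of these reached 2-fold. With arrays C and WT alone, chosen after seeing the data, 6807 genes were called, 6326 of them shared with the whole group. The added poly-A RNA gave 3' signals above 5' signals by 1.67 ± 0.55 (log2, SD, n = 4) at 240 min and 1.90 ± 0.07 (n = 2) at 360 min, against means of 0.99 to 1.20 at 0 to 120 min. Of 42 spike-in probe sets 4 were called at 240 min, 3 at 360 min and 0 at the earlier times. Arrays A and B of 240 and of 360 min carried the Y-linked Eif2s3y at 8.07 to 8.49, against 2.37 to 2.79 on the 20 others, and Xist, the transcript of the inactive X chromosome, at 4.90 to 5.66 against 9.80 to 11.12. These values go against the female label of those 4 arrays. The median SD of a gene within its group was 0.208 at 240 min and 0.0911 to 0.137 at the other times.

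**Figure D4:**
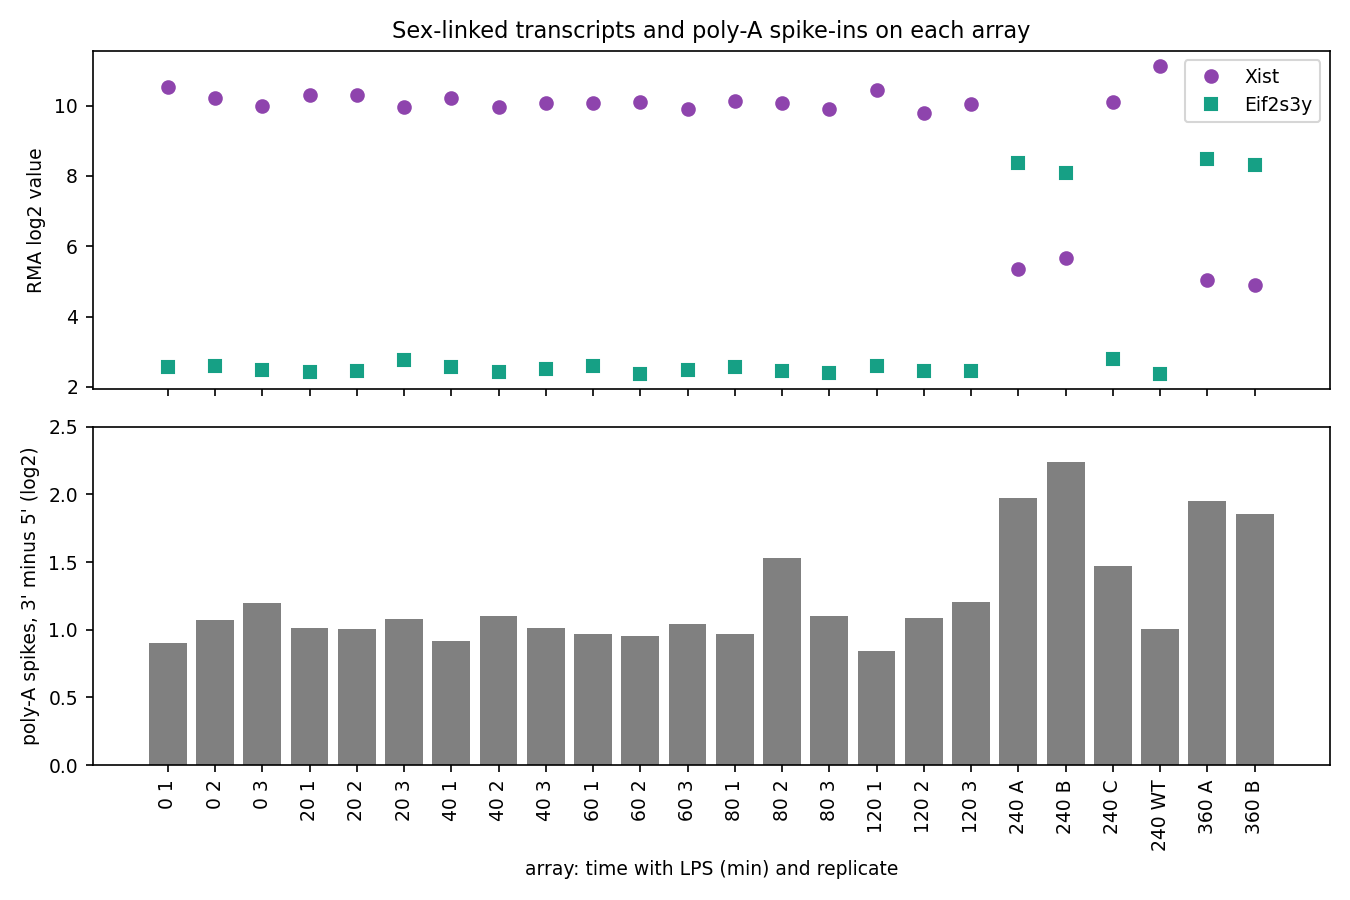
Log2 values of Xist and Eif2s3y, and the 3' minus 5' difference of poly-A spike-ins (log2), on each of the 24 arrays by LPS time. Arrays A and B of 240 and 360 min have Eif2s3y between 8.07 and 8.49 and Xist between 4.90 and 5.66, unlike the 20 others.

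At 360 min Acod1 stood 453-fold above unstimulated cells (8.82 ± 0.28, n = 2 and 3), from 4.78, just above the filter level. Ptgs2 (9.31 ± 0.19) and Ccl5 (8.97 ± 0.27), again from unstimulated values of 2.95 and 4.54, were also raised. Saa3 gained 8.40 ± 0.30, the lipase gene Lipg 8.16 ± 0.26 and Csf3, the gene of G-CSF, 1.95 ± 0.15 from an unstimulated value of 3.72, below the filter level. Among the falls were Slc40a1 (-5.90 ± 0.27), the iron exporter ferroportin, the ribonucleotide reductase gene Rrm2 (-5.75 ± 0.44), Gcnt1 (-5.29 ± 0.23) and Xist (-5.27 ± 1.03), beside the Y-linked signal on both arrays. Csf1r, the receptor of M-CSF, was not called (-0.17 ± 0.12, adjusted p = 0.230). Calls were 2586 higher and 4486 lower. Of the genes higher at 240 min 2056 were higher here, and of the lower ones 3971 were lower, where independent lists would share 552 and 1772. Simulated unchanged groups shared 0, without any effects, and how much the common unstimulated arrays add was not measured.

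By list, 40 of 40 interferon-stimulated genes (40 adjusted over the list alone; adjusted p = 9.10e-37), 21 of 21 NF-kB genes (21 adjusted over the list alone; adjusted p = 3.17e-17) and 14 of 14 nitric oxide and itaconate genes (14 adjusted over the list alone; adjusted p = 9.83e-11) were higher at 360 min. Cell cycle genes had 28 of 28 lower (28 adjusted over the list alone; adjusted p = 7.17e-10, and adjusted p = 0.115 with an estimated correlation). Of the macrophage identity markers and receptors 17 of 26 fell and 3 rose (18 and 4 adjusted over the list alone; adjusted p = 0.0476, and adjusted p = 0.304 with an estimated correlation). P2ry12 (-2.78 ± 0.21) and the scavenger receptor genes Cd163 (-2.76 ± 0.17) and Stab1 (-1.73 ± 0.33) were among those that fell, while the Fc receptor gene Fcgr1 rose (2.69 ± 0.15). Oxidative phosphorylation genes had 20 of 28 lower and 1 higher (21 and 1 adjusted over the list alone; adjusted p = 0.0149, and adjusted p = 0.598 with an estimated correlation).

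From 240 to 360 min Zmynd8 rose by 2.18 ± 0.14 (n = 2 and 4), Lhfpl2 by 2.63 ± 0.22 and Csf3 by 1.40 ± 0.14, and the GTPase gene Rhob (-3.07 ± 0.31), Arhgap18 (-2.34 ± 0.21), the transcriptional regulator gene Cited2 (-2.29 ± 0.22) and Rel (-1.29 ± 0.18) fell. These kept their calls in a fit to the late arrays alone (adjusted p = 0.0125 to 0.0376). At 240 min Csf3 (mean 4.27) and Lhfpl2 (3.54 to 4.42 on the single arrays) lay below the filter level, so the sizes of their rises depend on the background. Il10 (-1.46 ± 0.27), Hp (2.61 ± 0.41) and Lcn2 (2.01 ± 0.49) were called with the spread of all arrays (adjusted p = 0.000919, 0.000167 and 0.00723) and not with the late arrays alone (adjusted p = 0.101, 0.144 and 0.293). Lcn2 also lost its call without 360 min array A or B (adjusted p = 0.0750 and 0.0626). Xist fell by 3.09 ± 0.98 (adjusted p = 0.0353), with Y-linked signal on both 360 min arrays and on 240 min arrays A and B. Its call was lost with the late arrays alone (adjusted p = 0.429) and without 240 min C, 240 min WT, 360 min A or 360 min B (adjusted p = 0.0892, 0.0679, 0.190 and 0.157).

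The counts from 240 to 360 min were 909 higher and 1042 lower, 1951 in all, against 57 with the late arrays alone, 567 without 360 min array A and 1146 without B. Against 240 min arrays A and B alone, chosen after seeing the data, 1882 genes were called and 1303 were shared. Of 21 chemokines 7 were lower (8 adjusted over the list alone; adjusted p = 0.0335, and adjusted p = 0.853 with an estimated correlation), with Ccl7 at -0.94 ± 0.19. Among the 7, Cxcl11 (-1.78), Cxcl3 (-1.76) and Cxcl9 (-1.33) fell more, and they lost their calls with the late arrays alone (adjusted p = 0.289, 0.421 and 0.329). Over all comparisons camera called 98 of 189 pathway tests with the preset correlation, and 63 of these held with an estimated correlation.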

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

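The tests of handling, of sex, of spike-in signal, of array WT by itself and against the 20 min arrays below were chosen only after the results were seen. Of 59 values tested in the groups of 4 arrays, 5 had 1 array far from the others, where chance gives about 1 in 20.

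At 240 min array C had Il1b, the gene of interleukin 1 beta, at 12.30, below the 13.07 to 13.16 of the other 3 arrays. Array WT had Lhfpl2, which had the largest fall among the named genes at this time, at 3.54 against 4.41 to 4.42, all below the filter level. Array WT also had Ifnb1 at 8.81 against 4.60 to 5.19, and the stress-induced factor Atf3 at 11.35 against at most 11.06. Array B had its 75th percentile at 6.59 against 6.65 to 6.66. Jun changed in opposite directions between times, with 1.52 at 60 min and -1.13 at 120 min against unstimulated cells, and limma's test of the difference, 2.65, gave an adjusted p of 1.31e-08. That is the comparison of 120 and 60 min given above. Jun was picked for its opposite calls, so the test adds no further support. Outside the genes, the spike-in probe set BioDn-5, from added bacterial RNA, was higher by 0.96 at 240 min than in unstimulated cells (adjusted p = 0.00106).

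Genes called against unstimulated cells went from 1909 at 120 min to 7341 at 240 min and 7072 at 360 min. Loss of 5' signal as the whole cause was argued against by the 4761 genes called lower from arrays A and B alone. These had a median of -0.65 in arrays C and WT, and of -0.67 there against the 20 min arrays. The 20 min means were not in the comparison that chose the genes, though those arrays added to its estimate of the spread. Array C was itself low in 5' spike signal, at 5.76 against 5.50 on 80 min replicate 2 and 6.10 or more on the 17 other early arrays, but array WT, at 6.41, had a median of -0.73 (-0.75 against 20 min) with 94.1% of these genes lower. Cultures A and B alone were not the source, since arrays C and WT gave 6807 genes, and differences at single probes were argued against by a correlation of 0.840 between the 120 to 240 min changes of 2 probe sets of a gene over 4513 genes. Spike-in signal did differ, as 4 spike-in probe sets passed at 240 min against 0 at 20 to 120 min, and arrays A and B had Y-linked signal. Whether and how much another handling or other animals of the late cultures added to the response to LPS stays open. No unstimulated array of the late title pattern exists to separate them.

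Arrays A and B of 240 and 360 min had Y-linked signal and little Xist. Eif2s3y on the lowest of them lay 5.28 (log2) above the highest of the 20 others, while its second, dim probe set did not separate them (2.65 to 3.08 against 2.54 to 2.87), and male animals behind these arrays are a candidate explanation that goes against the female label. Of the other Y-linked genes, Uty separated them with each of its 4 probe sets (4.11 to 5.26 against 2.85 to 3.48 for the brightest), and Kdm5d with 1 of 3 (5.68 to 6.02 against 2.35 to 2.72). Male cells mixed into female cultures were argued against by Xist, whose highest value on the 4 arrays lay 4.14 below the lowest of the others. LPS for 4 h or more was argued against by arrays C and WT of 240 min, whose lower Xist value differed from the lowest of 0 to 120 min by 0.302.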

How the results depend on the processing

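Fits with parts of the 240 min group, and a fit without 80 min replicate 2 and 240 min B, were chosen after seeing the data. The last was meant to leave out low 5' spike signal. It kept 360 min A and B, whose 5' spike signals, 5.49 and 5.42, were below the 5.50 of 80 min replicate 2. Of 19017 values for 531 results of named genes, 18625 kept the call, 181 lost it, 209 gained it and 2 reversed. Direction was compared only where a gene was called in the first fit or the alternative, so uncalled genes may have changed direction among the 18625. Under every alternative run 438 results kept their call. The reversed results were Cebpd (-0.39) and Cxcl2 (-0.36) from 240 to 360 min with the letters A and B as block, with too few pairs to show that letters pair arrays. In that comparison the block gave 2547 genes against 1951.

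Counts over 1.5 times the first were, for 20, 40, 60, 80 and 120 min, 120 against 60 min and the F test, 29, 230, 846, 2099, 4600, 3953 and 4722 with the replicate block and 22, 192, 793, 1550, 4342, 4139 and 4682 with array weights. A random block gave 174, 578, 1311 and 3549 at 40, 60, 80 and 120 min and 2859 for 120 against 60 min. With 0 to 120 min arrays alone, 60, 80 and 120 min had 485, 1060 and 3187 and 120 against 60 min 2406. With the 2 groups alone 60 min had 522 and 120 against 60 min 2063. From 240 to 360 min the count was 57 with the late arrays or the 2 groups alone, where the median SD of a gene was 0.208 at 240 min against 0.0911 to 0.137 at the other times. The F test on 24 arrays called 1594 genes, and list tests called went from 98 to 63 with an estimated correlation. The cause of these changes was not tested. The replicate block ended no call among 347 results of named genes of 0 to 120 min and added 28, and beyond the lists named with the results it changed no other list call.

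Leaving out each array gave 11 to 18 genes at 20 min, 85 to 136 at 40 min, 228 to 385 at 60 min, 474 to 833 at 80 min, 1306 to 2373 at 120 min, 6756 to 7428 at 240 min and 5990 to 7325 at 360 min. It gave 778 to 1734 for 120 against 60 min (778 without 120 min replicate 2, 787 without 60 min replicate 1), 567 to 2397 for 360 against 240 min (567 without 360 min A, 1146 without B, where the lone array is assumed to vary like the other groups), and 1970 to 2861 for the F test. The highest counts at 40, 60, 80 and 120 min were those without 240 min WT. Signal near background limits the 6130 genes below the filter. Without the filter 7932 genes were called at 240 min, 7105 of them shared with the 7341.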

Other observations

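Genes of glucose use moved apart in the late samples, when 7341 (240 min) and 7072 (360 min) of all 12063 genes tested were called. Slc2a6, a hexose transporter, rose by 4.35 ± 0.15 at 240 min (limma log2 change and SE, n = 4 and 3) and by 4.69 ± 0.18 at 360 min (n = 2 and 3). Pfkfb3, which makes the activator of phosphofructokinase, rose by 3.78 ± 0.21 and 4.55 ± 0.25, and the hexokinase gene Hk2 by 2.39 ± 0.13 and 2.02 ± 0.15, while the aldolase gene Aldoa fell by 0.90 ± 0.13 and 1.24 ± 0.15. Of 19 listed genes 9 were higher and 8 lower at 240 min (9 and 8 adjusted over the list alone), and the list was not called (adjusted p = 0.0764). Among 13 targets of NRF2, the factor of the antioxidant response, 3 were higher and 6 lower at 240 min (3 and 6 adjusted over the list alone; adjusted p = 0.279). Hmox1, the haem oxygenase, fell by 2.54 ± 0.16 and Gclc, of glutathione synthesis, by 2.17 ± 0.24, while the cystine transporter gene Slc7a11 rose by 1.37 ± 0.17.

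Sterol genes also went both ways, at times when 7341 (240 min) and 7072 (360 min) of all 12063 genes tested were called. The cholesterol synthesis list had 1 of 19 higher and 7 lower at 240 min (0 and 4 adjusted over the list alone; adjusted p = 0.866), with Dhcr7 at -1.72 ± 0.24 and Mvk at -0.81 ± 0.12. At 360 min it had 7 higher and 4 lower (7 and 4 adjusted over the list alone; adjusted p = 0.288), with Fdft1 at 1.78 ± 0.39 and Hmgcs1 at 1.43 ± 0.44. From 240 to 360 min the list passed (adjusted p = 0.0140, and adjusted p = 0.853 with an estimated correlation) with 3 of 19 called (6 adjusted over the list alone). Among them Fdft1 and Mvd lost their call with the late arrays alone (adjusted p = 0.431 and 0.350) and without 360 min A (adjusted p = 0.256 and 0.279), and Fdft1 also without 360 min B (adjusted p = 0.125). The desaturase gene Scd2 of the LXR list fell by 3.44 ± 0.35 at 240 min while the lipid transfer gene Pltp rose by 1.08 ± 0.10. That list had 2 of 14 higher and 6 lower (2 and 6 adjusted over the list alone; adjusted p = 0.766).

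The numbered zinc finger genes of the Zfp family, many of which encode transcriptional repressors, were shifted downward against other genes at 80 and 120 min. At these times 21.2% and 38.2% of them were lower against 2.32% and 10.1% of all genes. The family was taken by symbol alone, so it also held the RNA decay gene Zfp36, which was higher at 80 min (12.48) than in unstimulated cells (8.23). Their 212 tested members had medians of 0.05 and 0.04 at 20 and 40 min with 0 lower, and -0.06, -0.20, -0.28 and -0.17 at 60, 80, 120 and 240 min (-0.07, -0.18, -0.26 and -0.14 after repeated quantile normalization), with 15, 45, 81 and 86 lower and 5, 9, 11 and 37 higher. At 360 min the median was -0.04 (0.03 after repeated quantile normalization) with 59 lower and 45 higher, after 27 rose and 9 fell from 240 min, and at 240 min the family was close to all genes (40.6% against 39.5% lower, all-gene median -0.12). Dim probe sets were argued against, since 0% of 10000 lists of other genes with matched mean levels had a median as low at 80 min, and without 80 min replicate 2 the median was -0.18. The 5 members among the named genes were Zfp36, which rose, and Zfp950, Zfp472, Zfp53 and Zfp748, which fell. Without these 5 the other 207 had a median of -0.19, and again 0% of matched lists were as low. The shift at 80 min may thus involve the family at large, a hypothesis found and tested on the same arrays with no test of transcript decay.

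Other splits of the arrays were fitted for each comparison with at least 3 arrays a side. The splits of 3 against 3 arrays number 10, too few for a share under 0.05. The real split alone, 1 of 10, gave as many calls in each, with 14, 109, 321, 682 and 1909 genes at 20, 40, 60, 80 and 120 min and 1336 for 120 against 60 min, and the highest other was 0, also among splits that part as many pairs of numbers. For 240 min against unstimulated cells 1 of 35 splits gave 7341 genes and the highest other 6227, which had array C on the unstimulated side. The 4 splits that differ from the real one in this way gave 4829 or more and the rest 4 or fewer. A random split of these arrays thus seldom gives as many calls, but every 240 min array has the late title pattern. The splits cannot tell LPS from that pattern. For the F test 1 of 100 draws, the real grouping, gave 2706 genes, with the highest other at 1237 and at 88 among draws within replicate numbers. A random grouping of these early arrays is thus argued against.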
